A study of Homo sapiens with 18 samples.

How the data were processed

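RNA from 18 cultures of human dermal fibroblasts, 1 commercial cell product, was hybridized to 18 Affymetrix U133 Plus 2.0 arrays, 1 per sample. The groups were 1 µM erlotinib (5 arrays), 100 nM erlotinib (5 arrays), DMSO (4 arrays) and no treatment (4 arrays). The treatment protocol states 5 dishes per group, so the others of the control groups were not analysed here. DMSO is stated as 1 µM, the figure of the higher dose, which is unclear as an amount of solvent, and the amount in the erlotinib dishes is not given in the sources used here. The values are log2 probe set intensities as deposited, which the authors made with RMA (background correction, quantile normalization and median polish). The RMA software, its version and the chip definition are not given in the sources used here. The scale was checked on the values, which ran from 2.97 to 15.3. Array medians still differed after RMA, from 6.35 to 6.51, so further scalings were tried. No coordinates are given because the genome build of the array annotation was not stated.

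Of 44758 probe sets 40736 had a single gene symbol, 1798 had several and 2224 had none. The Entrez ID of 49 of those with a single symbol was not found in the gene reference. Each of 19585 genes was represented by its probe set with the highest mean, and genes were tested when that mean was at least 6.43, the median over all probe sets. This left 11769 genes, 854 measured by a probe set ending in _x_at and 3474 by one ending in _s_at, which can measure related transcripts. X-inactivation and Y-linked genes were left out.

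limma 3.58.1 in R 4.3.3, with data.table at version 1.17.8, fitted 4 group means to all 18 arrays, with 14 residual degrees of freedom and a prior of 3.51. Moderated tests, two-sided, were made for 7 comparisons, and a moderated F test for any difference among the groups. A gene passed when its Benjamini-Hochberg adjusted p was under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

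In each comparison the genes named were the 12 largest rises and the 12 largest falls among genes past the threshold, and up to 2 members of each list past it. EGFR, DUSP6, SPRY4, CCND1 and MKI67 were named in each erlotinib comparison. Further list members were given as those with the largest change, and clone names were left out. This rule, the lists, the tests and most of the alternatives were fixed before the data were examined.

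The 20 gene lists covered signalling, cell cycle, stress, metabolism, matrix and secreted factors. Each was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, when at least 5 members were tested. Marker lists of fibroblasts and of 6 other cell types gave levels and changes without the floor. The correlation of the doses was set beside 100 simulations of unchanged groups sharing the DMSO arrays. Array medians and interquartile ranges were compared with exact two-sided permutation tests, 8 in all. A planned comparison of 3' and 5' control probe sets was not run, since the table held 0 of the AFFX control probe sets.

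The fit was tested on simulated data with 11769 genes in 5 simulations. It recovered 38.4% of genes changed by 0.25 on the log2 scale, 87.6% of those changed by 0.5 and 99.6% of those changed by 1. Of the calls 5.02% were false, and camera called 5 of 5 shifted lists and 0 of 95 unshifted ones. Genes were simulated as independent, while the estimated correlation within the G2/M list was 0.854. The simulation therefore does not show how often camera at its preset correlation calls correlated lists falsely.

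The alternatives were no floor, a floor at the 75th percentile, a further quantile normalization and median centring of each array. Others were eBayes with trend and robust, fits to the compared groups alone, array weights, other ways to use the probe sets, a pooled control, other thresholds, the replicate number as a block, and leaving out each array in turn. A fit without untreated replicate 1 and a correction of each array for genomic gene length were added after seeing the data.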

Results

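Cultured human dermal fibroblasts, the cells that make the collagen matrix of skin, were grown to confluence and exposed to erlotinib, an inhibitor of the tyrosine kinase of the epidermal growth factor receptor. The drug was given once a day for 3 days at 100 nM or 1 µM, and RNA was extracted on day 4. Control dishes received the solvent DMSO or no treatment. RNA abundance was read on 18 Affymetrix arrays, 5 for each dose, 4 for DMSO and 4 for untreated dishes. The comparisons ask which transcripts differ between erlotinib and its solvent, between the 2 doses, and between the solvent and no treatment. Array medians ran from 6.35 to 6.51 on the log2 scale, and the correlation between any 2 arrays ran from 0.971 to 0.997. No pair of arrays of a group was a duplicate, the highest correlation of their deviations from the group mean being 0.0869. The number of arrays limits the precision, and the cells were all one commercial product. P-values therefore measure the spread among these dishes, not among people.

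At 1 µM against DMSO, genes of DNA replication and mitosis fell, and most genes of the integrated stress and unfolded protein response rose while 6 fell. The largest falls were those of DIRAS3, a RAS-related GTPase (log2 fold change -2.67, SE 0.25, 6.36-fold), and CCNE2, a cyclin of the entry into S phase (-2.40, SE 0.22, 5.29-fold). The largest rises were those of GDF15, a stress-induced cytokine (1.96, SE 0.15, 3.89-fold), SEL1L3 (1.68, SE 0.12) and CHAC1, a glutathione-degrading enzyme (1.60, SE 0.13). In each of these 5 genes all 5 treated arrays lay beyond the mean of the DMSO arrays in the direction of the change. SLC7A11, the cystine transporter, reached 12.24 ± 0.06 (SD, n = 5) against 10.70 ± 0.33 (SD, n = 4) in DMSO. DIRAS3 and CCNE2 lay at 5.65 and 6.29 at 1 µM, under the floor of 6.43 used for testing, so their folds rest on dim signals on that side. CDC6 (5.88) and SEMA3A (6.09) lay under it at 1 µM too, and EPHA4 did in DMSO.

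**Figure D1:**
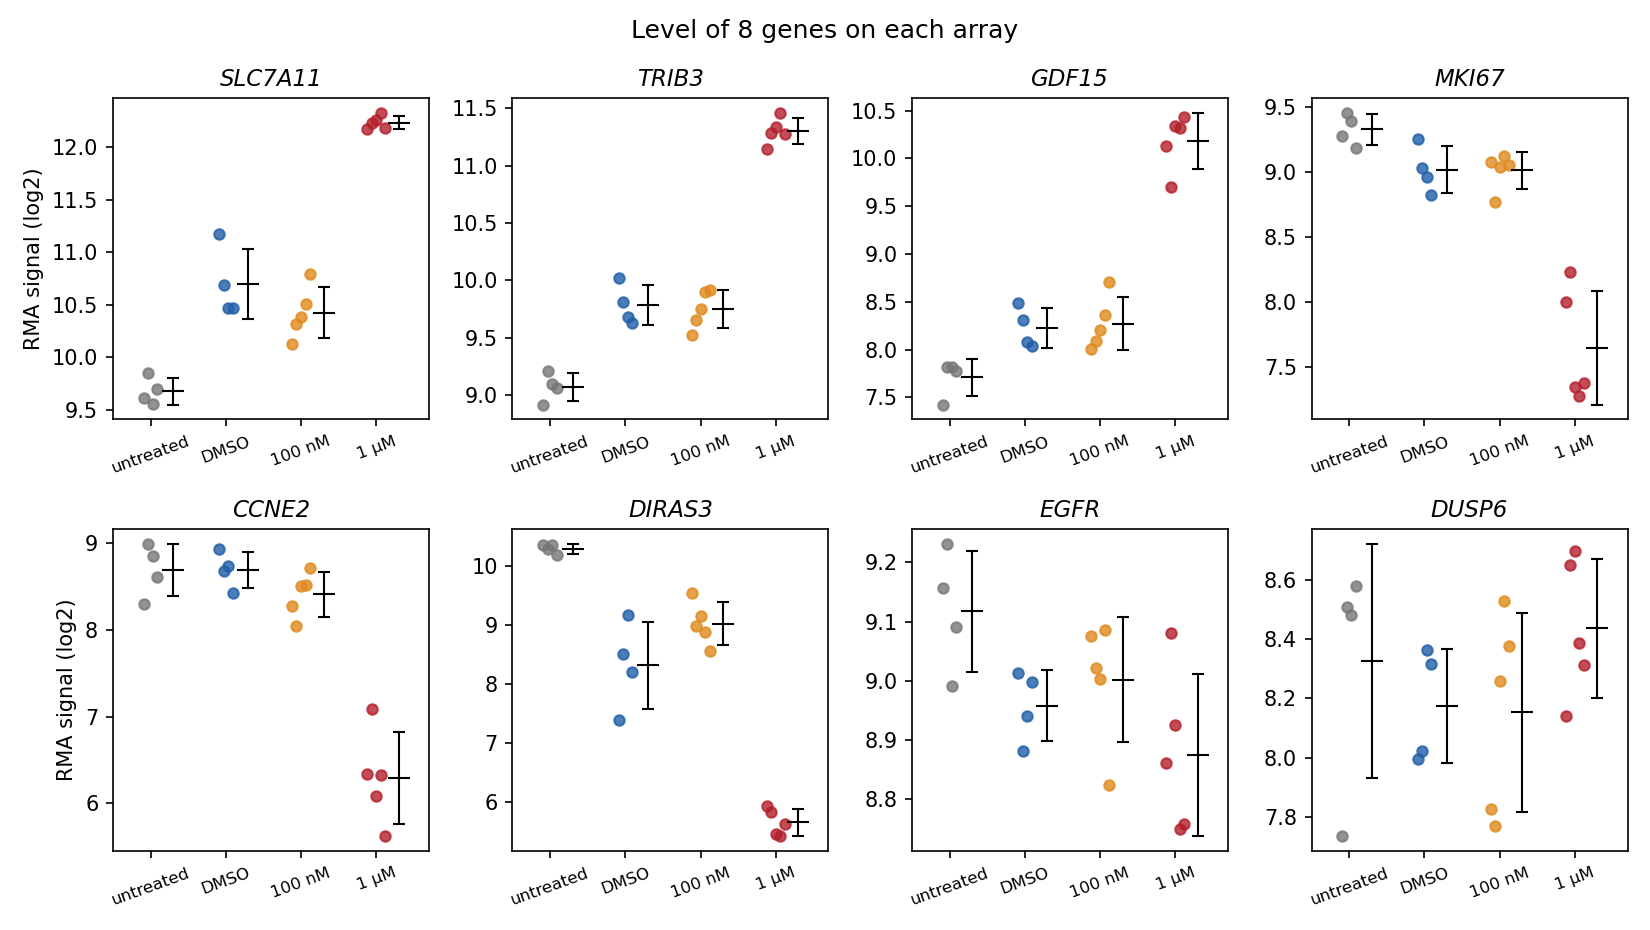
RMA signal on the log2 scale (vertical axis, a separate range for each gene) of 8 genes on each array of the 4 groups, with points for arrays and bars for the mean and SD of 4 or 5 arrays. SLC7A11, TRIB3 and GDF15 stood highest and MKI67, CCNE2 and DIRAS3 lowest at 1 µM, while EGFR and DUSP6 overlapped between DMSO and both doses.

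All 29 measured genes of the G2/M and mitosis list fell at 1 µM, with a median log2 fold change of -1.26. The arrays differed in extent, the mean deviation of the list from its mean over all arrays being -0.286 on 1 µM replicate 2 against -0.687 to -1.28 on the other 1 µM arrays, and 0.0409 on DMSO replicate 5 against 0.342 to 0.455 on the other DMSO arrays. The falls included ASPM (-1.50), BIRC5 (-1.49), AURKA, a mitotic kinase (-1.46), and the proliferation marker MKI67 (-1.37, SE 0.16). Of the 30 measured genes of S phase and DNA replication, 28 fell and 2 did not pass, with a median of -0.98, and 1 µM replicate 2 again changed least (-0.355 against -0.723 to -0.96). RRM2, a subunit of ribonucleotide reductase (-1.85), CDC6, which loads the replicative helicase (-1.75), and GINS2 (-1.67) followed CCNE2. The counts adjusted over the list alone were also 29 and 28. Both lists passed camera, the competitive list test of limma, with adjusted p = 3.3e-20 and 3.86e-20 at its preset correlation. With an estimated correlation the adjusted p = 0.192 for G2/M and 0.0824 for S phase, so neither call held. The spread of signal within an array, its interquartile range, was 3.34 ± 0.05 (SD, n = 5) at 1 µM and 3.43 ± 0.02 (SD, n = 4) in DMSO, a difference with adjusted p = 0.0318 in an exact two-sided permutation test.

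Of the 28 measured genes of the integrated stress and unfolded protein response, 18 rose, 6 fell and 4 did not pass at 1 µM (18 higher and 7 lower when adjusted over the list alone). The rises included TRIB3, a pseudokinase induced by the transcription factor ATF4 (1.52, SE 0.092), SESN2 (1.38), DDIT4, an inhibitor of mTORC1 signalling (1.33), and ATF4 itself (0.69). The 6 genes that fell encode proteins of the endoplasmic reticulum, mostly chaperones: SDF2L1 (-1.01), PDIA4 (-0.61), HSP90B1 (-0.52), HSPA5 (-0.43), CALR (-0.37) and DNAJC3 (-0.17). The list rose in camera with adjusted p = 1.67e-09, and 0.0462 with an estimated correlation. Among 19 measured p53 targets 11 rose and 1 fell (12 and 1 when adjusted over the list alone), with a list-adjusted p = 1.55e-08, and 0.0356 with an estimated correlation. After GDF15 the largest were ZMAT3 (0.88), MDM2, the ubiquitin ligase of p53 (0.57), and GADD45A (0.54), and the gene that fell was SERTAD1 (-0.27). Among 16 measured targets of AHR and NRF2 11 rose and 2 fell, the same counts as when adjusted over the list alone (adjusted p = 4.68e-08, and 0.0356 with an estimated correlation). PIR (0.97), ME1, an NADPH-producing enzyme (0.88), and AKR1C1 (0.75) rose beside SLC7A11, and AHRR (-0.27) and TIPARP (-0.18), which repress AHR, fell. SLC7A11 is also a member of the stress response list, so its rise does not point to AHR and NRF2 alone. The narrower interquartile range at 1 µM, 3.34 against 3.43, accompanied these groups too.

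Of 28 respiratory chain genes 15 fell at 1 µM and none rose, with ATP5MC1 (-0.37) and SDHA (-0.34) the largest (16 lower when adjusted over the list alone). Of 21 FOXO target and quiescence genes 9 rose and none fell, the same counts as when adjusted over the list alone, led by TSC22D3 (0.95) and the cell cycle inhibitor CDKN2B (0.52). Both lists passed camera (adjusted p = 0.000661 and 0.00274), and neither did with an estimated correlation (adjusted p = 0.408 and 0.361). Genes downstream of the receptor did not move as lists. Of 26 ERK outputs 3 rose, led by EPHA4 (0.76), and 4 fell, led by HMGA2 (-0.42), with list-adjusted p = 0.793. Of 15 ErbB receptors, ligands and regulators CBLB rose (0.48), and the ligand gene NRG1 (-1.53, SE 0.18) and GRB2 (-0.15) fell, with list-adjusted p = 0.699. The 2 lists gave the same counts when adjusted over the list alone. DUSP6 (0.26, SE 0.18), SPRY4 (0.01, SE 0.087), CCND1 (-0.07, SE 0.071) and EGFR (-0.08, SE 0.071) did not pass, with adjusted p = 0.306, 0.952, 0.525 and 0.41. Matrix protease genes went both ways, 7 higher and 7 lower (7 and 8 when adjusted over the list alone), with MMP12 (-1.96), ADAMTS1 (-0.84) and MMP1 (-0.71) the largest falls, SERPINE2 (0.61) and TIMP3 (0.54) the largest rises, and list-adjusted p = 0.976. COL15A1 (1.45) rose among 6 of 34 matrix genes that did (4 fell, the same counts adjusted over the list alone, and list-adjusted p = 0.277), while COL1A1 and COL1A2 did not pass (adjusted p = 0.961 and 0.933). Of the lists not past the threshold, cholesterol synthesis had 3 genes higher and 12 lower (4 and 12 adjusted over the list alone), hypoxia 3 and 14 (3 and 14 adjusted over the list alone) and TGF-beta response 7 and 1 (7 and 1 adjusted over the list alone), with adjusted p = 0.0758, 0.0554 and 0.0758. Paracrine growth factors had 4 higher and 9 lower (4 and 10 adjusted over the list alone, adjusted p = 0.261). Cytokines had 3 and 3 (adjusted p = 0.384), interferon-stimulated genes 3 and 2 (0.277), neurotrophic mediators 3 and 4 (0.819), clock genes 2 and 4 (0.699) and ribosomal proteins 0 and 0 (0.645), with equal counts adjusted over the list alone except 3 higher clock genes. The medians of the ERK, ErbB, interferon, neurotrophic, clock and ribosomal lists were below 0 where camera gave a rise, and those of all these but ERK changed sign under some scaling, as did that of the collagens. With no ribosomal gene past the threshold in limma, the whole comparison had 4647 genes at an unadjusted p under 0.05.

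In all, 3490 of 11769 genes passed in limma at 1 µM against DMSO, 1144 higher and 2346 lower, of which 29 and 126 changed at least 2-fold. The share of higher genes among them depended on scaling. It was 32.8% as deposited, 46.3% after a further quantile normalization and 49.7% after a correction for gene length chosen after seeing the data. Of the 54 named genes that passed, SEMA3A (-0.52) alone lost its call when some array was left out, at -0.41 (adjusted p = 0.0594) without DMSO replicate 1.

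At 100 nM against DMSO the changes were smaller. DMSO is stated as 1 µM, the figure of the higher dose, which is unclear as an amount of solvent, and the amount in the erlotinib dishes is not given in the sources used here. A difference in solvent therefore cannot be set apart from the drug in this comparison. The same holds for 1 µM against DMSO and for the 2 doses against each other. DMSO dishes differed from untreated ones in 602 genes. No gene that passed in limma changed 2-fold, and 255 genes passed, 197 higher and 58 lower, with 1639 at an unadjusted p under 0.05. The largest rises were those of NAA15 (0.96, SE 0.23), ZBED6 (0.90, SE 0.23), UBXN7 (0.81, SE 0.11) and the p53 target ZMAT3 (0.79, SE 0.12). EDN1, which encodes the vasoconstrictor endothelin-1 (0.76, SE 0.11), USP40 (0.73), SRRM2 (0.71), RSF1 (0.71), CDC42BPA (0.70) and LMO7 (0.69) also rose. LARP1B (-0.40), SNHG19 (-0.36), CEP19 (-0.35) and TTC14 (-0.33) fell most. MKI67 (-0.01, SE 0.16), EGFR (0.04, SE 0.071), DUSP6 (-0.02, SE 0.18), SPRY4 (0.01, SE 0.087) and CCND1 (0.10, SE 0.071) did not pass, with adjusted p between 0.591 for CCND1 and 0.992 for MKI67.

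Genes of the matrix and of contraction were shifted upward at 100 nM. Of 34 collagens and matrix proteins ELN, the gene of elastin (0.45), and POSTN (0.23) rose, and none fell (4 higher when adjusted over the list alone). Of 26 TGF-beta response and contractile genes CNN1 (0.47), TAGLN (0.30) and MYL9 (0.25), which encode proteins of the contractile apparatus, rose (4 when adjusted over the list alone). Of 12 neurotrophic and itch or pain mediators EDN1 and the neurotrophin BDNF (0.27) rose (4 when adjusted over the list alone). These 3 lists passed camera with adjusted p = 1.86e-08, 0.000329 and 5.47e-06, and with an estimated correlation adjusted p = 0.0432, 0.0432 and 0.0235. Paracrine growth factors, with FGF7 (0.46), INHBA (0.35) and SFRP1 (0.31) higher, and matrix proteases, with ADAMTS5 (0.32) higher, passed with adjusted p = 0.00287 and 0.00282 (5 and 2 higher when adjusted over the list alone). With an estimated correlation their adjusted p = 0.302 and 0.23. The lists of cholesterol synthesis and of hypoxia were higher, and those of the respiratory chain and of ribosomal proteins lower, with no member past the threshold. Their adjusted p = 0.0179, 0.0314, 0.00189 and 0.00282, and with an estimated correlation adjusted p = 0.302, 0.465, 0.465 and 0.465. Adjusted over the list alone, 5 respiratory chain genes and 1 ribosomal gene were lower, and no cholesterol or hypoxia gene passed. The medians of the stress response, p53 and FOXO lists lay below 0 and that of the ErbB list too, where camera gave a rise that did not pass. The hypoxia call was lost without DMSO replicate 1 (adjusted p = 0.117), DMSO replicate 2 (0.0733), 100 nM replicate 2 (0.0997) or 100 nM replicate 4 (0.0783). Without DMSO replicate 1 the calls of cholesterol synthesis (0.139) and matrix proteases (0.0691) were lost too.

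**Figure D2:**
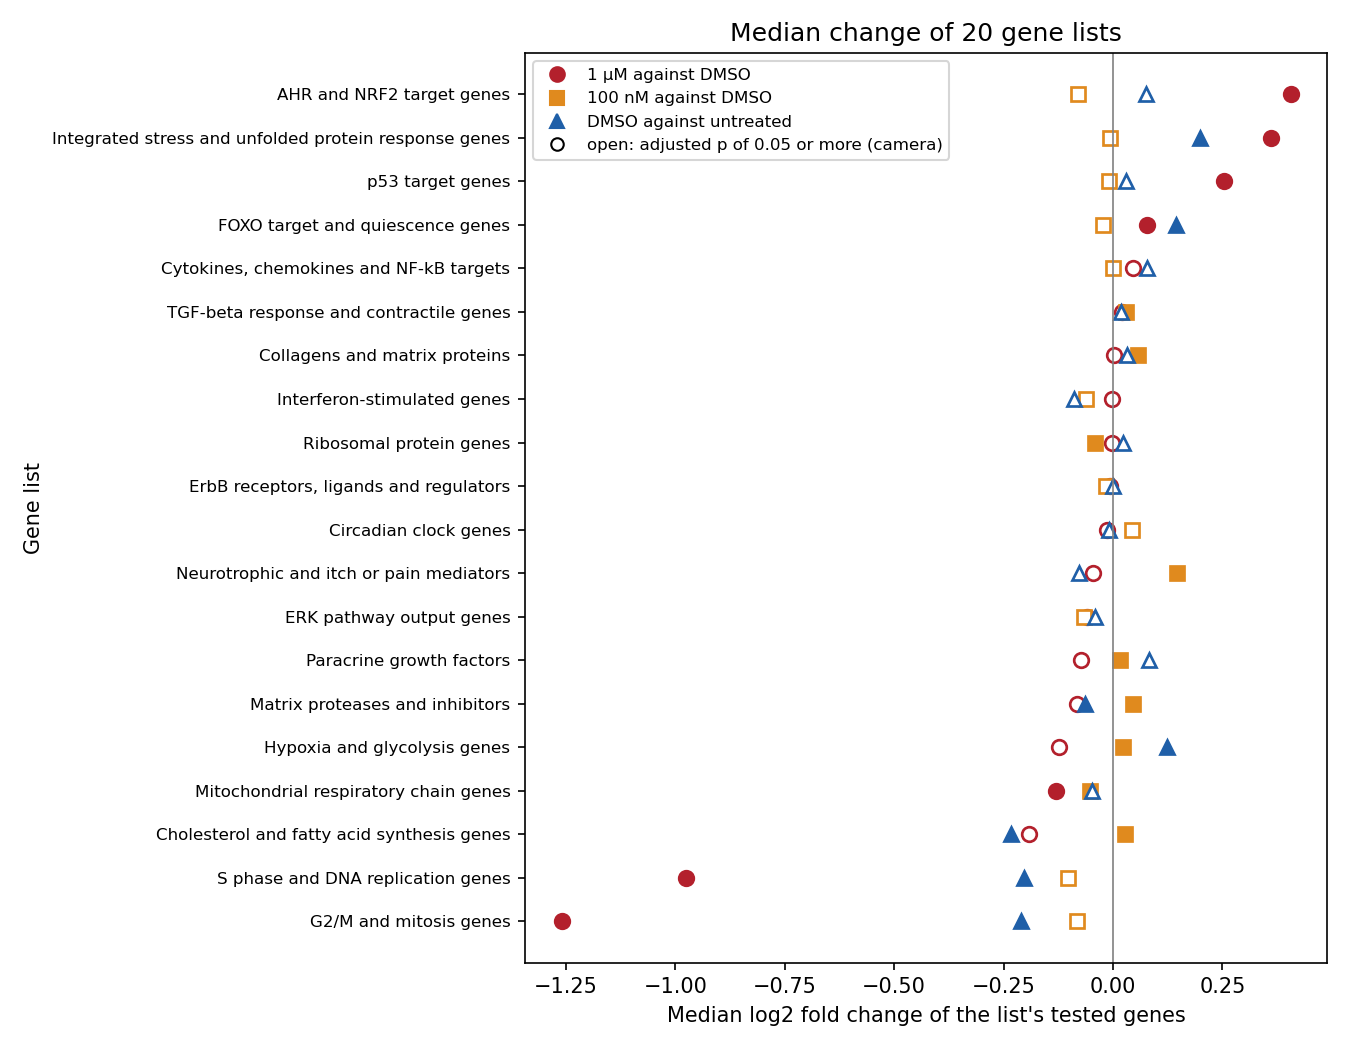
Median log2 fold change (horizontal axis) of the tested genes of 20 gene lists (vertical axis) in 3 comparisons, told apart by colour and shape, with filled symbols where camera passed at its preset correlation. The S phase and G2/M lists lay at -0.98 and -1.26 at 1 µM, while every list lay between -0.10 and 0.15 at 100 nM.

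The count at 100 nM rested on single arrays more than any other. It fell to 87 without DMSO replicate 2, 107 without DMSO replicate 5, 137 without DMSO replicate 4, 143, 144 and 109 without 100 nM replicates 1, 2 and 3. Of the 34 named genes that passed, 11 kept their call whichever array was left out, among them EDN1, UBXN7, ZMAT3, USP40, RSF1, CDC42BPA, TAGLN and ADAMTS5. The other 23 lost it without some array, among them NAA15, ZBED6, ANKRD36B, SRRM2, LMO7, LARP1B, CEP19, TTC14, CNN1, ELN, POSTN, FGF7, INHBA, BDNF and NQO1. The share of higher genes was 77.3% as deposited and 50.6% after a further quantile normalization.

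The 2 doses were then compared directly. Between 1 µM and 100 nM 3723 genes passed, 1554 higher and 2169 lower at 1 µM. DIRAS3 (-3.37, SE 0.23), MMP12 (-2.26), CCNE2 (-2.12), TSPAN13 (-2.09) and NRG1 (-1.79) had the largest falls, of which those of DIRAS3 and CCNE2 end under the floor at 1 µM and are uncertain in size and rank, and HAS2, a hyaluronan synthase, was lower too (-1.64, SE 0.10). GDF15 (1.91), SEL1L3 (1.81), SLC7A11 (1.81), NIBAN1 (1.59) and TRIB3 (1.55) were highest. All 29 G2/M genes and 28 of 30 S phase genes were lower at 1 µM, and 17 of 28 stress response genes were higher and 7 lower. These 3 lists had adjusted p = 2.08e-20, 2.06e-18 and 6.05e-07, and with an estimated correlation adjusted p = 0.157, 0.105 and 0.105. Adjusted over the list alone, the counts were 29, 28, and 17 with 8. Other lists that passed were AHR and NRF2 targets (12 higher, 2 lower), p53 targets (11 higher, 0 lower), FOXO targets (6 higher, 1 lower), cholesterol synthesis (1 higher, 16 lower), hypoxia (3 higher, 14 lower) and ribosomal proteins (2 higher, 0 lower). Adjusted over the list alone, these were 12 and 2, 12 and 0, 6 and 1, 2 and 16, 3 and 14, and 0 and 0. With an estimated correlation none of the 10 lists kept its call, the lowest adjusted p being 0.0691. Of 20 paracrine growth factors 4 were higher and 10 lower (5 and 10 adjusted over the list alone), with adjusted p = 0.0272, 0.37 with an estimated correlation, and 0.0538 without 1 µM replicate 2. MKI67 was lower (-1.37, SE 0.15), while DUSP6 (0.28, SE 0.17), SPRY4 (0.00, SE 0.082), CCND1 (-0.17, SE 0.067) and EGFR (-0.13, SE 0.066) did not pass. The interquartile range was 3.34 ± 0.05 (SD, n = 5) at 1 µM and 3.45 ± 0.04 (SD, n = 5) at 100 nM, with adjusted p = 0.0318 in an exact two-sided permutation test. The share of higher genes was 41.7% as deposited, 57.8% after a further quantile normalization and 53.4% after the length correction.

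Across the 11769 genes, which are not independent replicates, the log2 fold changes of the 2 doses against DMSO correlated with r = 0.217. Unchanged groups simulated against the same DMSO arrays gave a median r of 0.547 (0.223 to 0.787), and splitting the DMSO arrays between the doses gave r from -0.01 to 0.179. The covariance was 0.00656 against a simulated median of 0.00381, within the simulated range of 0.00142 to 0.00834. The sign was shared by 59.6% of genes against a simulated 69.4%. These simulations leave out the effects, and changes found at 1 µM alone can lower r and the shared sign. Values below the simulated ones therefore do not show that the doses agree less than unchanged groups would. Among genes past the threshold at both doses, 95 were higher at both and 28 lower at both. Independent lists would share 19.1 and 11.6, a value that leaves out the shared DMSO arrays, and 100 simulations of unchanged groups shared at most 1 and 0, a value that leaves out the effects. Over 6 splits of the DMSO arrays between the doses, which leave 2 arrays for each and 8 to 152 rises and 0 to 24 falls at 100 nM, 3 to 35 genes were higher at both and 0 to 4 lower. Independent lists of those sizes would share 0.464 to 9.87 and 0 to 3.01. A total of 24 genes passed in opposite directions. BDNF, CNN1, INHBA and SFRP1 rose at 100 nM and fell at 1 µM, and NQO1 fell at 100 nM (-0.22) and rose at 1 µM (0.49). NQO1 lay at 13.18 in untreated dishes, 13.46 in DMSO and 13.24 at 100 nM, so its fall ended near the untreated level. Of the 58 falls and 197 rises at 100 nM, 12 and 18 had passed the opposite way in DMSO against untreated, and 1 and 3 the same way. Lists independent of each other would share 1.21 and 5.96, and 1.75 and 4.12. The DMSO arrays, shared with opposite sign, favour opposite calls.

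**Figure D3:**
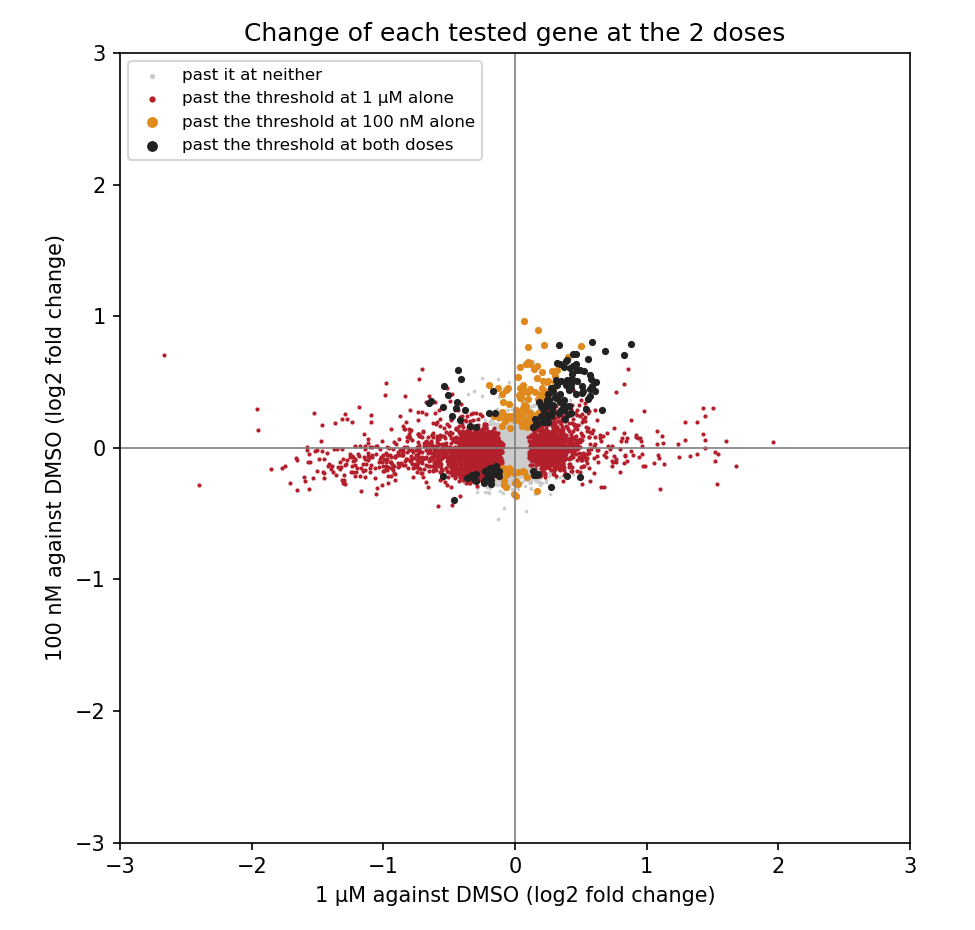
Log2 fold change against DMSO at 1 µM (horizontal axis) and at 100 nM (vertical axis), on equal scales, with 1 point for each of 11769 genes, coloured by whether it passed at both doses (147), at 1 µM but not 100 nM (3340), at 100 nM but not 1 µM (108), or at neither (8174). The points spread far wider along the 1 µM axis.

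The mean of both doses against DMSO gave 1709 genes, 514 higher and 1195 lower. Of the cell cycle lists, 28 of 29 G2/M genes and 26 of 30 S phase genes were lower (28 and 27 adjusted over the list alone), with adjusted p = 2.1e-17 and 4.53e-19, and 0.195 and 0.0756 with an estimated correlation. These falls rest on 1 µM. At 100 nM alone 0 of 29 and 0 of 30 passed in limma, also when adjusted over the list alone, with medians of -0.08 and -0.10 and 1639 genes of the whole comparison at an unadjusted p under 0.05. The 2 lists had adjusted p = 0.658 and 0.0537 at 100 nM, and 0.905 and 0.725 with an estimated correlation. CCNE2 (-1.34, SE 0.19, under the floor at 1 µM), RRM2 (-1.01) and NCAPG (-0.99) fell most. The stress response list had 16 genes higher and 4 lower (17 and 4 adjusted over the list alone), with adjusted p = 1.65e-11, and 0.0499 with an estimated correlation, where 100 nM alone had 1 higher (1 adjusted over the list alone) and adjusted p = 0.0858. GDF15 (1.00, SE 0.14), SCRG1 (0.91), ZMAT3 (0.84) and SESN2 (0.79) rose. ZMAT3 and CDC42BPA (0.77) lay above every DMSO array on 10 of 10 erlotinib arrays, and GDF15 on 6 of 10. MKI67 was lower (-0.69, SE 0.14), and DUSP6 (0.12), CCND1 (0.02), SPRY4 (0.01) and EGFR (-0.02) did not pass. Of 10 lists past camera, the stress response and the p53 targets (8 higher and 1 lower, 8 and 1 adjusted over the list alone, adjusted p = 0.0499 with an estimated correlation) kept their calls. The FOXO call was lost without DMSO replicate 4 (adjusted p = 0.0911), and that of the neurotrophic mediators without DMSO replicate 1 (0.0632) or 1 µM replicate 1 (0.0514). Without DMSO replicate 2 the count was 1013, and the share of higher genes was 30.1% as deposited and 44.3% after the length correction.

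DMSO dishes differed from untreated ones. The rises included SLC7A11 (1.02, SE 0.14, 2.03-fold), ASNS, asparagine synthetase (0.90, SE 0.079), SLC7A5, a leucine transporter (0.88, SE 0.12), and PSAT1, of serine synthesis (0.75, SE 0.096). VLDLR (0.90), SOST (0.81), IL20RB (0.80), COL4A1 (0.78) and TRIB3 (0.71) also rose. The largest falls were those of DIRAS3 (-1.98, SE 0.26, 3.94-fold), RCAN2 (-1.36), TMEM158 (-1.33), BAALC (-1.32) and the collagenase MMP1 (-1.16, SE 0.17). All 4 DMSO arrays lay beyond the untreated mean in each of these genes. Of 28 stress response genes 14 rose and none fell (15 adjusted over the list alone), with adjusted p = 2.36e-12, and 0.0256 with an estimated correlation. Of 25 cholesterol and fatty acid synthesis genes 10 fell and none rose (18 adjusted over the list alone), with INSIG1 (-0.49), SCD (-0.46) and ELOVL6 (-0.42) lowest, and with adjusted p = 2.36e-12, and 0.00386 with an estimated correlation. Of 22 hypoxia and glycolysis genes 6 rose (12 adjusted over the list alone), led by the glucose transporter SLC2A1 (0.49), with adjusted p = 3.19e-05, and 0.188 with an estimated correlation. Of 20 matrix proteases 6 fell (7 adjusted over the list alone), with adjusted p = 0.00104, and 0.188 with an estimated correlation. The S phase list was lower with 3 genes past the threshold (4 adjusted over the list alone) and the G2/M list with none (none adjusted over the list alone), with adjusted p = 1.25e-06 and 0.000143, and 0.444 and 0.653 with an estimated correlation. FOXO targets had 1 higher and 1 lower (4 and 2 adjusted over the list alone), with adjusted p = 0.00222, and 0.444 with an estimated correlation.

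In all 602 genes passed in limma between DMSO and no treatment, 246 higher and 356 lower. The count was 389 without DMSO replicate 1. Of 49 named genes that passed, 11 lost their call without some array, among them SLC2A1 and DDIT4. The share of higher genes was 40.9% as deposited and 30.8% with each array centred on its median.

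Against untreated dishes, 1 µM gave 5405 genes, 2183 higher and 3222 lower. DIRAS3 (-4.65, SE 0.25), MMP12 (-2.95), TSPAN13 (-2.52) and RGCC (-2.41) had the largest falls, of which those of DIRAS3 (5.65) and RGCC (6.30) end under the floor of 6.43 at 1 µM and are uncertain in size and rank. SLC7A11 (2.56, SE 0.13, 5.88-fold), GDF15 (2.48), SEL1L3 (2.26) and IL20RB (2.24) were highest. MKI67 (-1.68, SE 0.16), CCND1 (-0.28, SE 0.071) and EGFR (-0.24, SE 0.071) were lower with adjusted p = 1.97e-07, 0.00382 and 0.00911, and DUSP6 (0.11) and SPRY4 (-0.19) did not pass. At 100 nM 1539 genes differed from untreated dishes, 655 higher and 884 lower, and 979 without untreated replicate 4. SOST (1.10, SE 0.12), ANKRD36B (1.05), LMO7 (1.02) and CDC42BPA (0.99) were highest and RCAN2 (-1.38, SE 0.12), TMEM158 (-1.34) and DIRAS3 (-1.27) lowest. MKI67 (-0.32), DUSP6 (-0.17), SPRY4 (-0.19), CCND1 (-0.11) and EGFR (-0.12) did not pass. With the mean of its probe sets, CCND1 was instead higher (0.29) and passed (adjusted p = 0.0463 in limma). The stress response list had 17 genes higher and none lower at 100 nM (19 adjusted over the list alone), with adjusted p = 6.77e-15, and 0.0225 with an estimated correlation. Of 12 lists past camera at 100 nM, 3 kept their call with an estimated correlation. That of the interferon-stimulated genes did not (adjusted p = 0.375), and it was also lost without untreated replicate 5 (adjusted p = 0.0788). Of 9 at 1 µM, that of the TGF-beta response was lost without 1 µM replicate 5 (0.0513) or untreated replicate 3 (0.0558), and none of the 9 kept its call with an estimated correlation. The share of higher genes at 100 nM was 42.6% as deposited and 31.6% with each array centred on its median. At 1 µM it was 40.4% as deposited and 52.3% after the length correction. A moderated F test over the 4 groups gave 5128 genes.

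Marker genes of cell types were compared in a fit without the floor. At 1 µM against DMSO 11 of 12 fibroblast markers lay above the floor, of which PDGFRA (-0.24) and THY1 (-0.20) fell and none rose. Of the pericyte and smooth muscle markers ACTA2 (0.39) rose and CSPG4 (-0.52) fell, and at 100 nM MCAM rose (0.32). Of 11 keratinocyte markers 2 were above the floor and neither passed, while KRT5, below it at a mean level of 5.64, was higher at 1 µM (0.35). No marker of adipocytes (2 of 7 above the floor), endothelium (3 of 10), immune cells (1 of 9) or melanocytes and Schwann cells (3 of 7) passed in limma at either dose against DMSO. For both doses against DMSO CSPG4 (-0.31) and KRT10 (-0.18) were lower and ACTA2 (0.30) and MCAM (0.20) higher. At 1 µM against 100 nM PDGFRA (-0.28), THY1 (-0.32), S100A4 (-0.23), CSPG4 (-0.42), MCAM (-0.24) and NOTCH3 (-0.25) were lower and KRT5 (0.30) higher. THY1 (-0.41) and S100A4 (-0.44) were lower in DMSO than in untreated dishes. In the fit with the floor DCN (0.12) and KRT10 (-0.15) passed too at 1 µM against DMSO, COL3A1 (-0.09) and ACTA2 (0.17) between the doses and PECAM1 (0.29) for DMSO against untreated. In that fit THY1 (-0.61 at 1 µM, -0.29 at 100 nM) and S100A4 (-0.58, -0.35) were lower than in untreated dishes, among 10 and 7 markers that passed. Among others, the probe sets of DCN, MCAM, THY1, GDF15, NIBAN1, KLF4, SDHA, AKR1C1, RRM2, CDC6, MKI67, DIRAS3, NRG1, DUSP6, SPRY4, NAA15, UBXN7, EDN1, BDNF and ASNS are of the kinds that can also measure related transcripts.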

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

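The test of the size of the rises at 100 nM after median centring, the lengths of those genes and the test on the 4 less abundant fibroblast markers were chosen after the results were seen. An array stood far from the others of its group in 44 of 568 groups of 4 or 5 arrays, over 20 gene lists, the array summaries and the genes named, where chance gives about 1 in 20 groups, or 28.4. These values are log2 signals for genes, and for lists mean deviations of the members from their mean over all arrays.

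Untreated replicate 1 was the array most often apart among the lists. It stood low for the ERK list (-0.1022), the interferon list (-0.07853), the p53 list (-0.2607) and the ribosomal list (-0.03897). It was also low for ANKRD36B (7.873), DUSP6 (7.735), GDF15 (7.422) and SNHG19 (10.74). Untreated replicate 3 stood high for ELOVL6 (10.24) and EPHA4 (6.502) and low for SFRP1 (9.667).

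Among DMSO arrays, replicate 1 stood high for CDC42BPA (10.02) and LARP1B (7.498) and low for AHR (9.453) and MMP12 (8.315). Replicate 2 stood high for the cytokine list (0.06382) and low for BDNF (9.97). Replicate 4 stood low for CBLB (9.158) and IL20RB (7.933). Replicate 5 stood high for ADAMTS1 (11.95) and low for NCAPG (9.627) and the S phase list (0.08825).

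At 100 nM replicate 1 stood low for DCN (14.36), and replicate 2 for the G2/M list (0.14), BIRC5 (10.18), MKI67 (8.768) and MDM2 (8.366). Replicate 4 stood high for the hypoxia list (0.1586) and NOTCH3 (7.493). Replicate 5 stood high for ME1 (11.14) and NRG1 (9.254) and low for AHR (9.284) and AHRR (11.2).

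At 1 µM replicate 2 stood high for CDC6 (6.398) and MMP1 (11.23), and replicate 3 for the collagen list (0.06288). Replicate 4 stood high for PSAT1 (13.89) and low for BDNF (9.774), CDC42BPA (10.2), LMO7 (11.26) and RSF1 (9.389). Replicate 5 stood low for ASNS (13.16), CEP19 (7.027) and SLC7A5 (11.58).

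Genes that moved in opposite directions at the 2 doses against DMSO, with a difference between the doses that passed in limma, numbered 24, of which 7 were higher at 1 µM and 17 lower. The log2 difference of 1 µM minus 100 nM was -0.416 for BDNF, -1.01 for CNN1, -0.79 for INHBA, -0.86 for SFRP1 and 0.712 for NQO1. Both effects share the DMSO arrays, which moves them the same way and not apart.

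Probe sets with several genes or none were left out of the comparisons, and 1984 of them lay above the floor. Of these 517 passed in limma at 1 µM against DMSO, 75 at 100 nM against DMSO and 89 between DMSO and no treatment.

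Other splits of the same arrays tested how often relabelling alone gave as many genes. Such a test cannot set the treatment apart from other differences that follow the groups. Among those tried, the real split was the 1 split as large in 6 of the 7 comparisons and in the test of 4 groups. Its count and the highest other of 100 splits were 3490 and 2822 for 1 µM against DMSO, 255 and 2 for 100 nM against DMSO, 3723 and 3 for 1 µM against 100 nM, and 5405 and 4091 for 1 µM against untreated. They were 1539 and 476 for 100 nM against untreated, 5128 and 518 among the 4 groups, and 602 and 5 of 35 splits for DMSO against untreated. The splits with 2822, 4091 and 476 genes put 4 of the 5 erlotinib arrays together under the name of the controls, which is nearly the real split. For both doses against DMSO 3 of 100 splits reached 1709, the highest giving 3083 with 4 of the 1 µM arrays as the DMSO group, which points to the structure of the samples, the 1 µM arrays lying apart.

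The rises at 100 nM were weighed first. Their genes were long, with a median genomic length of 65.5 kb against 32.5 kb for random lists matched on expression. Correcting each array for a length trend left their median log2 fold change at 0.383 from 0.379. Over all genes the trend was small, with medians of -0.0349 under 10 kb and -0.00418 over 100 kb. This argues against a trend across all genes as the whole cause, while an effect on some long genes was not tested. The 17 measured nuclear-retained and detained-intron RNAs had a median of -0.033 (95% bootstrap interval -0.0659 to 0.0181 over these genes, not over dishes). This argues against more nuclear RNA only as far as these genes measure it. After median centring 146 of 197 still passed, between the bounds set beforehand, so that count leaves brightness open. The median fold was 0.377. Centring moves every gene by the difference of the mean array medians, 0.00139 here, so it tests only a uniform shift of that size. The other 51 calls ended. The median SE of the rises was 0.0768 before and 0.0808 after, and the cause of the loss was not tested. A response to the low dose may remain as a hypothesis, a different amount of solvent was not tested, and the dependence of the count on single arrays keeps it weak.

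The stress response genes higher in DMSO than in untreated dishes were weighed next. Their median log2 fold change was 0.612, and 0.566 without untreated replicate 1. That array did not stand apart for the whole stress list, at a mean deviation of -0.4187 against -0.4277 to -0.3294 on the other untreated arrays. Leaving it out could therefore change little, and the test decides nothing on an outlying array among the others. After median centring it was 0.59. Centring moves every gene by the difference of the mean array medians, 0.0219 here, so it tests only a uniform shift of that size. Across genes the change from untreated to DMSO correlated with that from DMSO to 1 µM at r = 0.436, where shared DMSO arrays alone gave a simulated median of -0.525 (-0.767 to -0.136). All 14 of these genes rose further at 1 µM and 0 passed in limma at 100 nM, where 1639 genes of the whole comparison had an unadjusted p under 0.05. The solvent and the 1 µM dose may share a direction of response, and a difference in handling between untreated and treated dishes was not tested.

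The fall of cell cycle genes at 1 µM was weighed last. The median log2 fold change of the 59 genes was -1.17, and -1.12 after the length correction, which argues against a length trend across all genes. After median centring it was -1.19. Centring moves every gene by the difference of the mean array medians, 0.0167 here, so it tests only a uniform shift of that size. The 11 fibroblast markers, at -0.0451, decide nothing on a lower share of fibroblasts, since 7 lie within 2 log2 units of the highest signal, where a fall can be compressed. The other 4 had a median of -0.163, and the 95% bootstrap bounds over these genes, not over dishes, were their lowest and highest values (-0.236 and 0.0513). Of the 4, PDGFRA (-0.236) and THY1 (-0.201) fell past the threshold. All 4 lay far above the median of the cell cycle genes, which argues against a lower share of fibroblasts as the cause of a fall of that size. These values are consistent with fewer cycling cells at 1 µM, as a hypothesis, and the number of cells in the dishes was not used here.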

How the results depend on the processing

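The fit without untreated replicate 1 and the gene length correction were chosen after seeing the data. Counts of genes past the threshold stayed within 1.5 times their reported value under the alternatives run, except where values follow, and for those the cause was not tested unless it is named.

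Testing each probe set by itself gave 5264 for 1 µM against DMSO, 852 for 100 nM against DMSO, 2846 for both doses, 8440 for 1 µM against untreated and 2947 for 100 nM against untreated, where more probe sets than genes are tested. A log2 fold change of at least 0.5 left, by construction, 583, 52 and 210 against DMSO (1 µM, 100 nM and both), 601 between the doses, 102 for DMSO against untreated, and 1108 and 180 for 1 µM and 100 nM against untreated.

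The count of 255 at 100 nM against DMSO moved under many of the other alternatives. It was 123 without a floor, 395 with the stricter floor, 496 after quantile normalization, 414 with trend and robust, 146 with the arrays of those groups alone, 471 with array weights, 535 with the pooled control and 433 at an adjusted p of 0.10. The pooled control gave 3728 for both doses. The count for DMSO against untreated was 960 after quantile normalization, 268 with the arrays of those groups alone, 979 with array weights, 380 with the mean of probe sets and 991 at an adjusted p of 0.10. Array weights gave 3012 for 100 nM against untreated.

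The replicate numbers did not pair the arrays, the median correlation of same-numbered pairs being -0.0038. With the number as a replicate block, 100 nM against DMSO gave 118 genes and 1 µM against DMSO 3174.

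Leaving out each array in turn gave 87 (without DMSO replicate 2) to 296 (without DMSO replicate 1) genes for 100 nM against DMSO, with 107 and 137 without DMSO replicates 5 and 4 and 143, 144 and 109 without 100 nM replicates 1, 2 and 3. It gave 1013 (without DMSO replicate 2) to 2002 (without 1 µM replicate 2) for both doses, 389 (without DMSO replicate 1) to 659 (without DMSO replicate 4) for DMSO against untreated, and 979 (without untreated replicate 4) to 1502 (without untreated replicate 1) for 100 nM against untreated. For 1 µM the ranges were 2892 to 3547 against DMSO, 3127 to 3640 against 100 nM and 4795 to 5272 against untreated. The correlation of the doses ran from 0.1809 (without 100 nM replicate 5) to 0.2936 (without DMSO replicate 1). It was 0.7051 with untreated arrays in place of DMSO, and 0.0809 with the DMSO arrays split between the doses. The value of 0.7051 cannot be read as agreement of the doses. Both changes share the untreated arrays and any effect of solvent or handling, and no unchanged groups were simulated for it.

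With an estimated correlation the lists past the threshold numbered 3 at 1 µM and 3 at 100 nM against DMSO, 0 between the doses, 2 for both doses, 2 for DMSO against untreated, and 0 and 3 for 1 µM and 100 nM against untreated. fry, which does not compare a list with other genes, gave 11 at 1 µM and 5 at 100 nM against DMSO.

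Of 384 results for named genes, 2 reversed, meaning that the direction changed and the value passed before or after the change of setting. Over the other alternatives, 4356 gene values stayed on their side of the threshold, 159 no longer passed and 11 newly passed, and 275 and 6 did so with an array left out. Of 140 list results the counts were 788, 73 and 31, and with an array left out 1320, 13 and 27. Values that stayed on their side can include changes of direction where neither value passed. CCND1 at 100 nM against untreated was 0.29 with the mean of probe sets and passed (adjusted p = 0.0463 in limma). AKR1C1 in that comparison was 0.12 without _x_at probe sets and did not pass (adjusted p = 0.358 in limma). The cholesterol list at 100 nM reversed with the pooled control, to -0.8004 as a signed log10 of its adjusted p (0.158). Signal over background limits the dim genes, and the falls of genes that end under the floor are the least certain.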

Other observations

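The tests of the members of the stress list that reside in the endoplasmic reticulum were chosen after the result was seen. The hypothesis that the 1 µM response is one to amino acid supply, driven by ATF4, was examined on gene lists outside those of the comparisons. Genes that respond to ATF4 could rise whatever activates it, so their rise cannot tell amino acid supply from another cause. The tRNA synthetases that respond to ATF4 rose more than other cytosolic synthetases. Their median log2 fold changes differed by 0.675 (one-sided exact permutation test of gene labels, p = 0.0017). That test treats genes as independent, so its p does not measure the spread among dishes. Of 11 measured ATF4-responsive synthetases 10 rose, among them WARS1 (1.08), SARS1 (0.60) and GARS1 (0.55). Of the 6 others 0 rose and 4 fell, among them FARSB (-0.44) and VARS1 (-0.35). The list of amino acid transport and serine synthesis had a median of 0.414, with 9 of 14 higher and 2 lower (p = 0.0217 in camera of limma with an estimated correlation), led by CTH (1.45), SLC38A1 (1.12) and SLC1A4 (0.96). CTH encodes neither a transporter nor an enzyme of serine synthesis, so the list is wider than its name. These 2 lists were higher in DMSO than in untreated dishes too in camera of limma with an estimated correlation, with 7 of 11 synthetases higher (median 0.208, p = 0.00672) and 6 of 14 transport and serine genes higher and 1 lower (median 0.29, p = 0.0318), so the rise is not found with the drug alone. Lysosome and autophagy genes, at 0.0364 with 6 of 23 higher and 1 lower, left open whether they rise.

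Within the stress list itself, the members that reside in the endoplasmic reticulum lay -1.3 below the integrated stress members in median log2 fold change at 1 µM against DMSO. This split was made after seeing which members fell, so the difference restates that and tests nothing. Of the 11 such members 6 fell and 3 rose, with a median of -0.173 (p = 0.143 in camera of limma with an estimated correlation). Against 100 nM, 7 were lower and 3 higher at 1 µM, with a median of -0.267 (p = 0.037 in camera of limma with an estimated correlation). At 100 nM against DMSO their median was 0.0545 (p = 0.039 for a rise in camera of limma with an estimated correlation), with 0 of 11 past the threshold in limma and 1639 genes of the whole comparison at an unadjusted p under 0.05. The members went both ways and were picked on these arrays, so whether the unfolded protein response as a whole changed at 1 µM stays open. The integrated stress members had 15 of 17 higher, and 12 of 17 in DMSO against untreated dishes.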
